A study of Homo sapiens with 6 samples.

How the data were processed

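Gene expression was measured on 6 Affymetrix PrimeView arrays, 3 of TamR cells given a nonsense control siRNA (NS) and 3 of TamR cells given an siRNA against the androgen receptor gene AR. TamR is a tamoxifen-resistant derivative of MCF7, a human breast cancer cell line with estrogen receptor. Per the labels' protocols, RNA was taken 48 h after transfection from cells kept in RPMI medium with 10% serum, 20 mM HEPES, 0.28 IU/ml insulin and 5 µM of tamoxifen or its 4-hydroxy form, which the labels name differently in different fields. The labels state 10 nM for the control siRNA.

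The deposited values are log2 values, 1 per probe set and array, made by the authors. Per the series' design text, the array scans were processed with affy and limma in R 3.4.3, and the 3 samples of a group were biological replicates. The background correction, the normalization between arrays and the summarisation of probes to probe sets are not given in the sources used here. The log2 scale was read from the values, which lay between 1.42 and 14.0 on every array. Array medians lay between 5.14 and 5.17, so a shift of all genes in one direction would not be visible.

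Of 49293 probe sets, 44988 had 1 gene symbol in the platform annotation, 1832 had several and 2473 were unnamed here. Through the RefSeq gene table of assembly GRCh38.p14, 44961 of the single-symbol probe sets matched a current gene record, 27 did not, and 0 symbols changed. No genome build is named with the values, so no coordinates are given. Each of 18132 genes was represented by its single-symbol probe set with the highest mean over the 6 arrays, and 11734 genes had more than 1 probe set. The annotation listed 0 probe sets for AR, so the level of the siRNA's own target was not analysed here and the knockdown was not checked. Of the genes written into the lists, 47 had no single-symbol probe set under the symbol used and were not analysed here.

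The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, AR siRNA minus NS, no covariates, two-sided). Genes past a Benjamini-Hochberg adjusted p of 0.05 were called changed, with no fold threshold. Standard errors are those of the limma fit, and intervals cover 95%. Adjusted p-values of genes are from this fit. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so single genes were tested only through the model. The number of arrays limits the precision.

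Written before the data were examined, 26 gene lists with 596 distinct genes were tested with camera, a limma test of a list against the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of these genes, 549 were measured. The same test with an estimated correlation, and fry, which tests whether a list moves one way on balance without comparing it with other genes, were run beside it. For each list, called members were counted over all genes and adjusted over the list alone. Named genes followed a rule fixed beforehand. It takes the 10 largest changes in each direction among called genes that have no overlap between the groups and a mean above the median gene. It also takes up to 4 members per list, those with the largest changes among called members or, without any, the 2 with the smallest p as values only. ESR1, PGR, FOXA1, GATA3, ERBB2, MYC, CCND1 and MKI67 were allowed whatever their values, and AR was to be reported first.

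The procedure was tested on simulated data for this comparison over 18132 genes, in 10 simulations with 200 changed genes each. It recovered 64.0% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2. Unchanged genes made up 5.67% of its calls, and it made 0 calls where nothing was changed. The simulated genes were drawn independently of each other, so these rates do not cover correlated genes or effects shared by an array. The arrays were checked for duplicates: at most 0.623% of probe sets had equal values in any pair of arrays.

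Alternatives covered the replicate number as a block, the mean of all probe sets or every named probe set in place of the brightest, and probe sets with shared-sequence suffixes left out. They also covered dim genes left out, another normalization between arrays, other variance models, array weights, stricter thresholds and leaving out each array. Genes with only suffixed probe sets, among them DENND6A, PTPMT1, SRXN1, P4HA1, UGT2B15, NOP56 and SPRY4, were not tested without such probe sets. Alternatives for the AR knockdown and a search for siRNA seed matches in transcripts were not run.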

Results

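The data were genome-wide transcript levels in tamoxifen-resistant MCF7 breast cancer cells (TamR) 48 h after transfection with an siRNA against AR, the gene of the androgen receptor, or with a nonsense siRNA (NS). There were 3 arrays per group. The arrays resembled each other closely across genes, with correlations of 0.995 to 0.997 within groups and 0.989 to 0.993 between them. The first principal component held 56.5% of the variance and the second 19.3%. The comparison asks which genes depend on AR in cells that grow in the presence of tamoxifen. The siRNA's target itself was not analysed here, because the annotation lists no probe set for AR. All changes below are those of the arrays labelled AR siRNA against the arrays labelled NS.

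After AR siRNA, 16 of 22 measured p53 target genes rose, and 17 of 29 measured genes of DNA replication and 17 of 29 of mitosis fell. Among changed genes brighter than the median gene and without overlap between the groups, the largest increases included the receptor tyrosine kinase gene MET and the tetraspanin gene TSPAN8. The largest decreases among them included the chemokine gene CXCL8 and the mitotic genes HMMR and CENPA. Over all genes, log2 changes ranged from -2.96 to 2.89. In all, 2123 of 18132 genes (11.7%) changed at an adjusted p under 0.05 in limma, 1046 higher and 1077 lower. A change of at least 2-fold was seen in 225 of them, 108 higher and 117 lower, and the median absolute log2 change of the changed genes was 0.54. The values of the groups did not overlap in 2122 of the changed genes and in 29.0% of all genes, where chance gives 10%. The count fell to 1146 without AR siRNA replicate 2, to 1361 without NS replicate 1 and to 1372 without NS replicate 3.

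Among brighter genes without overlap, the largest increase was that of PGM2L1, which rose 4.64-fold (log2 change 2.21 ± 0.10, SE). TSPAN8 rose 4.50-fold (2.17 ± 0.14), and MET, the hepatocyte growth factor receptor, rose 4.25-fold (2.09 ± 0.09). BANF1, a DNA-binding protein of the nuclear envelope, rose 3.49-fold, the D-type cyclin CCND3 3.42-fold and the mitochondrial phosphatase PTPMT1 3.42-fold. All 3 probe sets of PTPMT1 carry the shared-sequence suffix, so PTPMT1 was not tested without such probe sets. The p53-induced SESN1 rose 3.30-fold and AKR1C3, an enzyme of androgen synthesis, 3.27-fold. PIP4K2A rose 3.13-fold. ANTXR1 rose 3.16-fold on its brightest probe set, 1 of 4, and was no longer called without probe sets of shared sequence (log2 change 0.18, adjusted p = 0.311).

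CXCL8, which encodes interleukin 8, showed the largest decrease under the same rule, with a log2 change of -2.81 ± 0.29 (SE). Its level went from 8.91 ± 0.26 (SD, n = 3) in NS to 6.10 ± 0.68 (SD, n = 3). HMMR, a spindle-associated protein, changed by -2.39 ± 0.15, and CENPA, the centromeric histone H3 variant, by -2.16 ± 0.11. DENND6A changed by -2.31 ± 0.12 on its only probe set, which carries the shared-sequence suffix. TTF2 (-1.96), ERLIN1 (-1.95), NIPSNAP2 (-1.90), the replication initiation factor MCM10 (-1.88) and FAM98A (-1.87) followed. TMPO, the gene of lamina-associated polypeptide 2, changed by -1.84, and was no longer called on its brightest probe set without shared sequence (-0.34, adjusted p = 0.136). Of its 9 probe sets 6 were called lower, 4 of them without the shared-sequence suffix, at -1.76, -0.86, -0.73 and -0.68. The adjusted p of these 20 genes was at most 0.00037. Of the 18 with more than 1 probe set, 15 had at least 2 called the same way and 0 had one called the other way. Agreement was lower over all changed genes. Of the 1615 changed genes with more than 1 probe set, 836 had at least 2 called the same way. In 21 of the 1615, another probe set was called the other way.

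Of 22 measured p53 targets, 16 rose and 0 fell, and 19 rose when adjusted over the list alone. The median log2 change of the list was 0.69 (camera adjusted p = 2.3e-13, and adjusted p = 0.377 with an estimated correlation). SESN1 (1.72 ± 0.11, SE) was followed by TP53INP1 (1.29 ± 0.09), by the cyclin-dependent kinase inhibitor CDKN1A (1.19 ± 0.10) and by the pro-apoptotic BAX (1.14 ± 0.08).

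Of 29 measured genes of DNA replication and E2F targets, 17 fell and 0 rose, and 23 fell when adjusted over the list alone. The median log2 change was -0.41 (camera adjusted p = 1.1e-14, and adjusted p = 0.377 with an estimated correlation). MCM10 had the largest change, followed by cyclin E2 (CCNE2, -1.14 ± 0.14, SE), the ribonucleotide reductase subunit RRM2 (-1.01 ± 0.11) and UHRF1 (-0.80 ± 0.14), which maintains DNA methylation. Of 29 measured G2/M and mitosis genes, 17 fell and 0 rose, and 21 fell when adjusted over the list alone. Their median was -0.42 (camera adjusted p = 1.0e-14, and adjusted p = 0.377 with an estimated correlation). Beside HMMR and CENPA, the kinase NEK2 (-0.80 ± 0.11) and cyclin A2 (CCNA2, -0.76 ± 0.12) fell. MKI67, the gene of the proliferation marker Ki-67, had a log2 change of -0.22 ± 0.09 on its brightest probe set and did not pass (adjusted p = 0.175). That probe set changed least of the 6 for MKI67. The other 5 had log2 changes between -0.75 and -0.46, and 2 of them, at -0.67 and -0.72, were called lower in the fit over all named probe sets. The number of fallen replication genes was 10 without NS replicate 3. That of mitosis genes was 9 without AR siRNA replicate 2, 10 without NS replicate 3 and 11 without NS replicate 1.

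**Figure D1:**
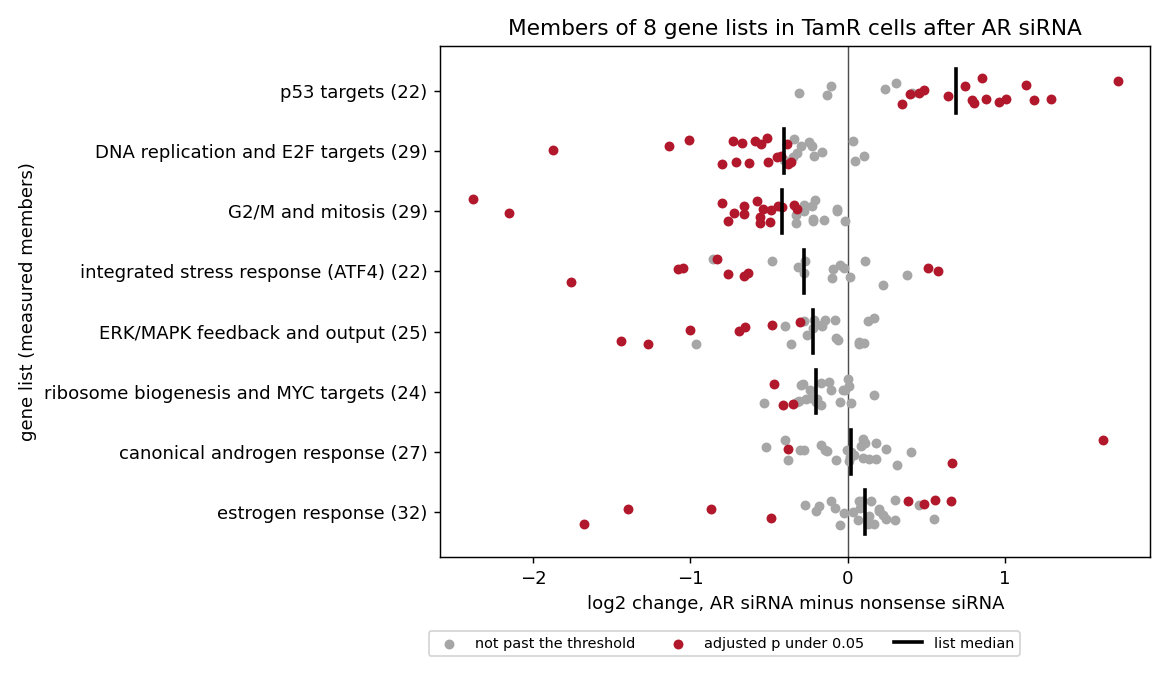
Each point is a measured member of a gene list, placed by its log2 change (AR siRNA minus nonsense siRNA, horizontal axis) with lists on the vertical axis, red where the adjusted p is under 0.05 and grey otherwise, and a black bar at the list median. The median lies at 0.69 for p53 targets, at -0.41 for replication genes and at 0.02 for the androgen response.

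**Figure D2:**
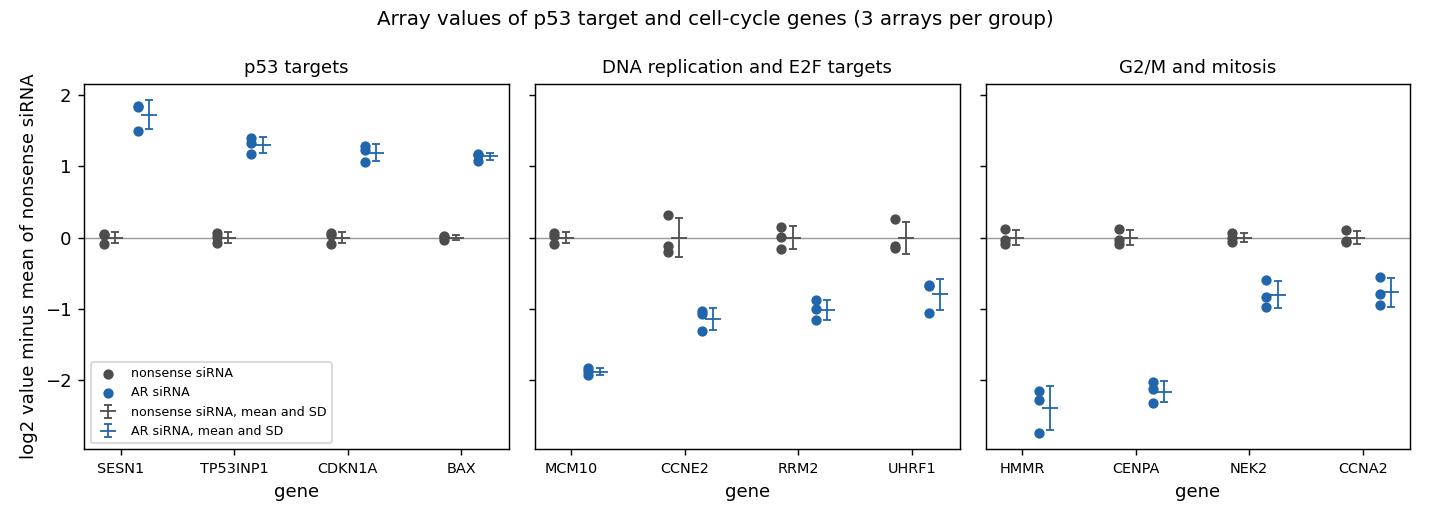
Points are the 3 arrays of each group, as log2 value minus the mean of the nonsense siRNA arrays (vertical axis) for 4 genes of each of 3 lists (horizontal axis), with the mean and SD beside them. SESN1 lies 1.72 above the nonsense siRNA mean and HMMR at -2.39.

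Of the other lists, 3 were called lower by camera with the preset correlation. The same 3 were not called by fry. Its adjusted p was 0.054 for the ATF4 list, 0.068 for ERK/MAPK output and 0.080 for ribosome biogenesis. Of 22 measured genes of the ATF4 integrated stress response, 7 fell and 2 rose, and 9 fell and 3 rose when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.0027, and adjusted p = 0.651 with an estimated correlation). The fallen genes included the mitochondrial folate enzyme MTHFD2 (-1.76 ± 0.10, SE), the cystine transporter SLC7A11 (-1.08 ± 0.19), ATF3 (-1.05 ± 0.13) and the dim CTH (-0.83 ± 0.14). The list was not called without genes dimmer than the median gene (adjusted p = 0.137), and 1 gene rose without NS replicate 2, NS replicate 3, AR siRNA replicate 2 or AR siRNA replicate 3. With the mean of all probe sets of a gene, 4 rose and 8 fell. Of 25 measured genes of ERK/MAPK output, 7 fell and 0 rose, and 9 fell when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.000157, and adjusted p = 0.608 with an estimated correlation). ETV4 (-1.44 ± 0.10), SPRED1 (-1.27 ± 0.17) and SPRY4 (from 7.39 ± 0.06 to 6.39 ± 0.45, SD, n = 3) had the largest changes, and 4 genes fell without AR siRNA replicate 2. Of 24 measured genes of ribosome biogenesis, 3 fell and 0 rose, where 11.7% of all genes changed, and 6 fell when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.000157, and adjusted p = 0.661 with an estimated correlation), with NOP56 at -0.47 ± 0.08 and WDR12 at -0.41 ± 0.08. The fallen genes numbered 2 without NS replicate 1, NS replicate 3, AR siRNA replicate 1 or AR siRNA replicate 2. They numbered 5 with the mean of all probe sets or a further quantile normalization, and 8 without genes dimmer than the median gene.

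The canonical androgen response list was not shifted (camera adjusted p = 0.964, median 0.02). Of its 27 measured genes, 2 rose and 1 fell, with the same counts when adjusted over the list alone. The prostaglandin-degrading enzyme HPGD rose (1.62 ± 0.10, SE), as did PLPP1 (0.67 ± 0.09), while 0 genes fell without NS replicate 1, AR siRNA replicate 2 or AR siRNA replicate 3. The molecular apocrine breast markers were not shifted either (adjusted p = 0.964), with 2 of 21 higher, among them the steroid-conjugating UGT2B15 (0.78 ± 0.13), and 2 lower, or 1 lower without any one NS array or AR siRNA replicate 2. Their median and mean lay just below 0 and the test just above it.

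ESR1, the gene of estrogen receptor alpha, rose 1.87-fold (log2 change 0.90 ± 0.11, SE, adjusted p = 0.00081), from 8.17 ± 0.12 (SD, n = 3) in NS to 9.07 ± 0.14 (SD, n = 3). All 5 of its probe sets had positive log2 changes, between 0.24 and 0.97, and 3 were called. The 32 measured estrogen response genes were not shifted together (camera adjusted p = 0.534, median 0.11), with 4 higher and 4 lower, or 7 and 4 when adjusted over the list alone. The count of risen genes was 2 without any one NS array or AR siRNA replicate 2, and the count of fallen genes was 4 without any one array. With the mean of all probe sets 7 rose. The potassium channel gene KCNK5 (-1.67 ± 0.22), the protease gene PRSS23 (-1.40 ± 0.14) and the carbonic anhydrase gene CA12 (-0.87 ± 0.16) fell, and the receptor tyrosine kinase gene RET rose (0.66 ± 0.10). KCNK5 was called on 1 of its 2 probe sets, with -0.15 on the other. PGR, the progesterone receptor gene, was dim and had a change of 0.55 (adjusted p = 0.054). FOXA1 (0.03), GATA3 (-0.14), ERBB2 (-0.08), MYC (0.07) and CCND1 (0.13) did not pass. Of 22 steroid receptors and cofactors, 3 rose and 2 fell (camera adjusted p = 0.309), including the thyroid hormone receptor gene THRB (-0.82 ± 0.10). The risen genes numbered 4 without AR siRNA replicate 1 and 2 without any other one array. They numbered 5 of the 16 left without genes dimmer than the median gene. With the mean of all probe sets 1 fell. Of 25 luminal markers, 1 rose and 2 fell (adjusted p = 0.980), or 1 fell without NS replicate 1, NS replicate 2 or AR siRNA replicate 3.

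TGF-beta and SMAD targets missed the threshold (camera adjusted p = 0.060), with 5 of 21 lower and 1 higher. CCN2, the connective tissue growth factor gene, had the lowest log2 change of any gene, -2.96 ± 0.34 (SE), and the inhibitors of differentiation ID1 (-1.45 ± 0.13) and ID3 (-1.12 ± 0.15) also fell, as did CCN1 (from 8.98 ± 0.21 to 7.98 ± 0.22, SD, n = 3). The list was called without NS replicate 1 (adjusted p = 0.033), NS replicate 3 (0.040), AR siRNA replicate 2 (0.016) or AR siRNA replicate 3 (0.028), and 2 genes rose without AR siRNA replicate 1. Of 31 interferon-stimulated genes, 5 fell and 0 rose, among them PARP9 (-0.90 ± 0.16) and IFIT5 (-0.64 ± 0.10). In this list 2 genes fell without NS replicate 3 or any one AR siRNA array. Of the 5 members left without genes dimmer than the median gene, 3 fell and 1 rose. The list was not called (adjusted p = 0.110) except without NS replicate 2 (0.022). Of 22 NF-kB genes, 1 rose and 1, CXCL8, fell (adjusted p = 0.964); the list's median was 0.02, its mean -0.09 and the test's direction up. Of the arrays left out singly, NS replicate 3 alone left the risen gene called, and 0 rose without each of the others. Among 15 genes of the RNA interference machinery, TNRC6C (1.05 ± 0.08) and TNRC6A (0.77 ± 0.10) rose (adjusted p = 0.301, and 0.049 without AR siRNA replicate 1). TNRC6C, a dim gene, was called on 1 of its 3 probe sets and TNRC6A on 4 of 6.

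In the remaining lists, members moved in both directions or few moved. Aryl hydrocarbon receptor and NRF2 targets had 5 of 18 higher, led by AKR1C3 and the dim aldehyde dehydrogenase gene ALDH3A1 (1.40 ± 0.18, SE), and 2 lower, SRXN1 (-1.10 ± 0.09) and SLC7A11 (camera adjusted p = 0.411). The risen genes numbered 2 without NS replicate 1, NS replicate 3, AR siRNA replicate 2 or AR siRNA replicate 3, and the fallen genes 3 without NS replicate 2. Of 21 PI3K/AKT/FOXO genes, 6 rose and 1 fell (adjusted p = 0.411), with PIK3R3 at 1.01 ± 0.09, FOXO1 at 0.73 ± 0.12 and the insulin receptor gene INSR at -0.83 ± 0.09. In this list 3 genes rose without AR siRNA replicate 2, 4 without NS replicate 1, NS replicate 2 or AR siRNA replicate 3, and 2 fell without NS replicate 1 or AR siRNA replicate 3. Of 18 BCL2 family genes, 4 rose and 1 fell (adjusted p = 0.337), with BAX, MCL1 (0.89 ± 0.11) and BIK (0.60 ± 0.12) higher, and 0 fell without NS replicate 1, NS replicate 3, AR siRNA replicate 1 or AR siRNA replicate 2. Hypoxia genes had 3 of 23 higher and 4 lower (adjusted p = 0.663), with KDM3A at 0.99 ± 0.09 and ERO1A at -0.75 ± 0.13. Without NS replicate 3 or AR siRNA replicate 2, 1 hypoxia gene rose and 1 fell, and 1 rose and 3 fell without NS replicate 2 or AR siRNA replicate 3. The count of risen genes was 2 without AR siRNA replicate 1. Unfolded protein response genes had 3 of 20 higher and 2 lower (adjusted p = 0.411), including SEL1L (1.01 ± 0.10) and PDIA4 (0.67 ± 0.08). The fallen genes of that list numbered 4 without genes dimmer than the median gene, 1 without NS replicate 2 or AR siRNA replicate 3 and 0 without any other one array. In cholesterol synthesis, 1 of 19 genes rose, or 0 without any one array, and 1, IDI1 (-0.96 ± 0.10), fell (adjusted p = 0.942). In fatty acid synthesis, 3 of 18 rose, among them ACSL1 (0.54 ± 0.09), or 1 without any one array, and 1, ELOVL6 (-0.78 ± 0.08), fell (adjusted p = 0.964). The medians of both lipid lists were above 0 and their means and tests below it.

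Markers of other cell types gave no called list. Mesenchymal and fibroblast markers had 2 of 23 higher and 1 lower (camera adjusted p = 0.852), with ACTA2 at 1.15 ± 0.17 (SE), a dim gene no longer called without probe sets of shared sequence (0.13, adjusted p = 0.685). The risen mesenchymal genes numbered 1 without NS replicate 3 or AR siRNA replicate 2 and 3 without AR siRNA replicate 3, and 0 fell without NS replicate 1, NS replicate 2 or AR siRNA replicate 2. Basal markers had 2 of 14 higher (adjusted p = 0.411), but 0 without NS replicate 1 or AR siRNA replicate 2, 1 without NS replicate 3 or AR siRNA replicate 3 and 3 without AR siRNA replicate 1. Of 19 immune markers, 0 passed (adjusted p = 0.852), with ITGAM at 0.25 and LYZ at 0.23, and 1 fell without AR siRNA replicate 1. Of 17 ERBB receptors and ligands, 0 passed (adjusted p = 0.538), with EREG at -1.08 (adjusted p = 0.089) and HBEGF at -0.28. The log2 change of EREG was negative on 1 of its 4 probe sets and that of HBEGF on 1 of 2. With genes dimmer than the median gene left out, 2 of 14 androgen response, 1 of 9 apocrine and 2 of 19 cholesterol genes fell. Of the fatty acid genes 3 of 15 fell, and of the BCL2 family 2 of 14. In the same setting 1 of 14 androgen response, 2 of 19 cholesterol, 2 of 25 luminal and 1 of 5 basal genes rose. Also risen were 2 of 5 NF-kB, 2 of 15 TGF-beta and 1 of 13 RNA interference genes. Only 1 mesenchymal gene was left, and it was not called. With the mean of all probe sets, 0 androgen response, 1 luminal, 2 fatty acid and 2 BCL2 family genes fell, while 1 fatty acid, 1 mesenchymal, 2 NF-kB and 2 TGF-beta genes rose. Of the 26 lists, 6 were called with the preset correlation and 0 with an estimated one, while fry called 4: p53 targets (adjusted p = 0.0094), replication and mitosis genes (0.016 each) and TGF-beta targets (0.021). Before adjustment, camera p also rose in some lists whose estimate lay below the preset 0.01. It went from 0.016 to 0.058 for TGF-beta targets (estimate -0.013) and from 0.233 to 0.274 for basal markers (-0.034). It fell slightly for estrogen response (0.329 to 0.326), cholesterol (0.761 to 0.757) and fatty acid genes (0.868 to 0.866), also below the preset. The lost calls thus cannot be put down to correlation alone and do not decide whether the lists moved.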

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

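Except for the count over other splits of the arrays, the tests in this part were chosen after the results were seen. For the p53 inhibitors and the dim probe sets, a looser criterion was replaced by a stricter one after its outcome was seen, as stated beside each. Probe sets outside the comparison of named genes also changed: 181 of 2473 probe sets with no gene name here (7.32%) and 133 of 1832 with several gene names (7.26%) passed the adjusted p of 0.05 in a fit over all probe sets, against 9.10% of those with 1 name.

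The 6 arrays can be split 3 against 3 in 10 ways. The real split gave 2123 genes, as many as 1 of the 10 splits, its own, and the highest count of the other splits was 0. With 10 splits the share cannot fall under 0.05.

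After AR siRNA, 16 of 22 p53 targets rose and 17 of 29 replication and 17 of 29 mitosis genes fell, and the 3 lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.377 each). A shift tied to probe brightness is argued against by 10000 random lists of matched brightness, whose highest median log2 change was 0.24 against 0.69 for the p53 targets and whose lowest was -0.16 against -0.41 for the 58 replication and mitosis genes. A single deviating array is argued against as well. Without any one array, the list median stayed between 0.59 and 0.74 for p53 targets. It stayed between -0.46 and -0.33 for replication genes and between -0.46 and -0.36 for mitosis genes. Called members numbered as few as 12 p53, 10 replication and 9 mitosis genes in these fits. The highest adjusted camera p of the 3 lists was then 1.1e-10 with the preset correlation. With all arrays it was at most 2.3e-13, so this p says little by itself. Silencing of a p53 inhibitor by the siRNA stays open. Of 7 inhibitors MDM4 fell (-0.47, 1 of its 6 probe sets), and RCHY1 (0.67) and MDM2 (0.40) rose. MDM2 is also on the list of p53 targets, so its rise is part of the pattern. The fall of MDM4 met a first criterion of any fallen inhibitor but not the stricter one of more than chance gives. In draws of 7 genes, 1 or more fall in 34.9%. Silencing of 1 inhibitor alone could thus not meet the stricter criterion, which cannot decide the question. A loss of AR, a general response to this siRNA and an effect on growth cannot be told apart. The arrays hold no second AR siRNA and no measure of growth, and seed matches of the siRNA were not searched for.

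ESR1 was higher while the estrogen response list was not shifted. A single aberrant ESR1 probe set is argued against, because the other 4 probe sets had a median log2 change of 0.46 and 2 of them were called. Whether AR loss raised ESR1 stays a hypothesis and was not tested further.

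The androgen response list was not lower after AR siRNA. Dim probe sets could hide a decrease. The 14 members brighter than the median gene had a median log2 change of 0.0535, with quartiles of -0.24 and 0.16. Without genes dimmer than the median gene the list was not shifted (camera adjusted p = 0.897, direction up). The bright members thus did not fall as a set. They went both ways, however, and the test leaves open whether dim members hide a decrease. A first criterion, which allowed a lower quartile further below 0, was met and would have argued against dim probe sets. A failure to silence AR also stays open, since the annotation lists 0 probe sets for AR and the knockdown was not measured here. The medium's content of androgens was not tested either.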

How the results depend on the processing

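All alternatives were chosen before the data were examined. The count of changed genes, 2123, stayed within 1.5 times under the mean of probe sets, left-out dim genes or shared-sequence probe sets, other normalizations, variance trends and array weights, between 1684 and 3063. It was 4146 (2025 higher, 2121 lower) over all named probe sets, where more features are tested, 898 (414 and 484) with a 1.5-fold threshold and 907 (425 and 482) at an adjusted p of 0.01, where the criterion is stricter. Leaving out 1 array, which leaves fewer samples, gave 1146 to 1695 changed genes, 566 to 781 higher and 580 to 968 lower. The share of higher genes ranged from 42.9% to 50.6% over the alternatives that fit genes, against 49.3%. With the replicate number as a block 2363 genes changed, and 6 lists were called, as without it. The deviations of same-numbered arrays correlated at 0.31, 0.20 and -0.02, and 3 of 6 arrays matched their own number best, which leaves pairing open. Of the 6 called lists, 0 were called with an estimated correlation (0.166 to 0.445, preset 0.01), which correlation alone may not explain.

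Of 94 called named genes, 73 held without each array and 21 did not: ACACA, CAV2, CLDN7, COL3A1, DHRS2, EAF2, HRK, IFIH1, ISG20, LSS, ME1, MXI1, MYLK, NFKBIE, P4HA1, PUS7, RAB4A, SDF2L1, SESN3, SPRY2 and TGFBI. Calls were lost without shared-sequence probe sets for ANTXR1, TMPO (4 dimmer probe sets without shared sequence were called lower), ACTA2, RARA, COL3A1 and PUS7. With the mean of probe sets they were lost for TFAP2A, RARA, RAB4A, IFIH1, ACACA, ME1 and COL3A1. At an unchanged log2 change, the adjusted p moved to between 0.052 and 0.066 for IFIH1 and ME1 without shared-sequence probe sets, for IFIH1, LSS, ME1 and CAV2 over all named probe sets, and for ISG20 and ME1 with the block. ME1 had 0.29 (0.058) with median centring. ACACA turned from 0.37 to -0.10 with the mean of probe sets, where another of its probe sets is called the other way. Among uncalled genes, LYZ turned to -0.0917 and HBEGF to 0.0863 without shared-sequence probe sets, and MYC to -0.0055 with array weights and between -0.0302 and 0.143 without 1 array.

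Uncalled lists near 0 also turned direction, and the cause was not tested. The adjusted p was 0.992 for apocrine and for NF-kB genes with the block, 0.986 for NF-kB genes after quantile normalization, 0.975 for mesenchymal markers without genes dimmer than the median gene and 0.929 for ERBB genes with the mean of probe sets. Without 1 array the adjusted p ranged from 0.829 to 0.997 for the androgen response, 0.513 to 0.944 for apocrine, 0.635 to 0.926 for cholesterol, 0.745 to 0.997 for fatty acid, 0.859 to 0.997 for luminal, 0.513 to 0.898 for immune and 0.574 to 0.898 for NF-kB genes. TGF-beta targets were called with the mean of probe sets (0.033) and had 0.566 without genes dimmer than the median gene. Counts of changed members also moved. With the block 3 androgen, 2 ERBB and 5 ribosome genes fell, and 1 ATF4 and 1 interferon gene rose. After quantile normalization 2 BCL2 genes fell. The alternatives for the AR knockdown were not run, as AR was not analysed here. Low signal limits dim genes: 370 changed genes lay below the median gene.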

Other observations

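The test in this part was chosen after the data were seen, among gene families formed by the letters of a symbol before its first digit or hyphen. Of 247 families with at least 10 genes, 2 passed camera. The 24 genes of the family NUP are mostly nucleoporins, which build the nuclear pore, but include the pseudogene NUP210P1 and the paralogues NUP210L and NUP62CL. Of the 24, 7 fell, NUP62CL among them, and 0 rose, with a median log2 change of -0.20. NUP93 changed by -0.73 ± 0.09 (SE), NUP50 by -0.61 ± 0.09, NUP155 by -0.52 ± 0.09 and NUP85 by -0.46 ± 0.08, all chosen after their values were seen. The adjusted camera p of the family was 0.0069 with the preset correlation, and the lowest of any family was 0.99 with an estimated one, so a joint decrease of this group may be stated only as a hypothesis. A first criterion asked for the preset correlation alone and was met, and the estimated correlation was added as a requirement after that was seen. The other root that passed was MCM (adjusted p = 0.019), with 3 of 11 genes lower, MCM6, MCM7 and MCM10. These 11 include MCM3AP and the antisense RNA MCM3AP-AS1, which are not MCM helicase genes, and several of the rest are in the replication list.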
